A study of Arabidopsis thaliana with 14 samples.

How the data were processed

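RNA was sequenced from whole rosettes of Arabidopsis thaliana plants that were 3 weeks old and had grown under 12 h of light at 22 °C by day and 19 °C by night. Per the labels' protocols, plants were sprayed with 50 µM estradiol in 0.001% Silwet-L77, a wetting agent, or with water and the same agent, and rosettes were harvested 3 h later. Each replicate was a pool of 5 rosettes. Libraries were made from 100 ng of total RNA with the TruSeq RNA kit v2, which does not mark strand, so reads from a gene and from an overlapping or antisense gene could not be told apart.

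Per the submitters' processing notes, the reads passed through FastQC, TopHat2, SAMtools and HTSeq against the TAIR10 build. Tool versions, the handling of reads with several matches and the counting mode were not given in the sources used here. The deposited values were whole-number counts of reads per gene, made by the authors with no normalization visible in the files. Each file listed 33602 genes with coordinates, of which 279 were organelle genes, and all rows named a gene. The total count per library lay between 20456036 and 20789232 in 12 libraries and was 22565424 and 22605970 in replicates 2 and 1 of line N2102363. File names marked the libraries of both lines, but not those of Col-0, as combined, and replicate 4 of both lines carried a date that no other file name carried. What combined refers to, and whether libraries were cut to similar totals, was not given in the sources used here.

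Samples were grouped by their titles into Col-0 sprayed with water (n = 3), Col-0 sprayed with estradiol (n = 3), and estradiol-sprayed plants of the inducible WRKY75 lines N2102362 (n = 4) and N2102363 (n = 4). Line plants sprayed with water were not analysed here. The labels call the samples biological replicates; the study's design text gives 4 for the lines, while the protocol for RNA extraction names 3, and the sources do not resolve what replicate 4 was. No libraries of a group were near copies of each other: the lowest chi-square per degree of freedom between libraries of a group was 14.4, and correlations of log2 CPM within groups ran from 0.957 to 0.989.

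All 14 libraries entered 1 fit in edgeR 4.0.16 under R 4.3.3. The filter filterByExpr, with its minimum count of 10 and smallest group of 3, kept 19666 genes and removed 13936. Libraries were scaled by TMM and tested by the robust quasi-likelihood F test, with group as the sole factor and 10 residual degrees of freedom. The biological coefficient of variation was 0.196. A gene was called when its p adjusted by the Benjamini-Hochberg method was under 0.05, and the number of called genes with an absolute log2 fold change of at least 1 was counted beside it. Every adjusted p of a single gene printed here comes from this test unless DESeq2 is named. Standard errors of log2 fold changes were taken from the F statistic. Values per library are CPM, the count scaled to a fixed TMM-adjusted library total, where 1 count corresponded to about 0.05 CPM; errors of group means are SD between libraries.

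The comparisons were estradiol against water in Col-0, each line against Col-0 sprayed with estradiol, the mean of both lines against Col-0 sprayed with estradiol, and line against line. The groups, comparisons, tests, gene lists, naming rule and most alternatives were set before the data were examined. The naming rule took WRKY75 in every comparison. For the mean of the lines it took up to 10 genes per direction with the largest fold changes among genes also called in each line, with a mean CPM of at least 1 and no overlap between the compared groups. For estradiol in Col-0 and for line against line it took up to 6 per direction by the same measures. From each gene list with called members it took up to 4 of these, and uncalled members could be named with their values. No list had a called member, so the list members named below were chosen after their values were seen, for a large change or as examples of a known function. AT2G01008 was called but fell outside the rule and is named because few genes were called.

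For 21 gene lists covering hormones, defence compounds, stress, nutrition, the clock, photosynthesis, other WRKY genes and markers of floral, root, guard, vascular and dividing cells, 342 of 374 entries were measured. Some genes stood in more than 1 list. Lists were tested against all other genes with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the 21 lists within a comparison, and again with the correlation estimated from the data. The preset treats genes of a list as nearly independent, and with the estimated correlation 0 lists were called in every comparison. The test fry asked whether the genes of a list moved 1 way on balance, without setting them against other genes. Counts of called members were also made with p adjusted over the list alone. List members were not searched for near-identical copies, and families such as LHCB1, RBCS, AOC and KIN hold close relatives whose separate values are uncertain.

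Gene names and promoter sequences came from the reference annotation TAIR10.1, which matched 32835 genes by locus tag; 10599 of these had the same start and end in both sources, so gene coordinates below are those of the count files, counted from 1, and promoters were taken upstream of the gene start in the reference. The W-box (TTGACC or TTGACT on either strand) was searched in the 500 bp upstream and compared by a Fisher's exact test. Called genes were matched to all other genes with BLAST 2.17.0, and a match of at least 95% identity over at least 100 bases counted as near-identical. Scripts were tested on simulated counts with 200 changed genes per comparison. At an absolute log2 fold change of 1 the fit recovered 61% of changed genes for estradiol in Col-0, 76% for N2102362, 76% for N2102363, 72% for the mean of the lines and 74% for line against line. At 2 it recovered 86%, 98%, 97%, 96% and 98%. These simulations, run on 19553 to 19564 genes, describe genes with the simulated spread. Some genes were not called at larger changes, such as AT2G01008 at -2.82 ± 0.43 (SE) in N2102363.

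Alternatives were median-of-ratios and upper-quartile scaling, no filter on low counts, a filter on CPM of at least 1 in 3 libraries, DESeq2 1.42.0, a fit of the compared groups alone, a replicate block, an adjusted p under 0.01, both Col-0 groups as reference, and leaving out each library or replicate 4 of both lines. Added after the data were seen were an indicator for replicate 4 of both lines, independent Col-0 controls for the lines, a camera test of all genes with a W-box, and the W-box count without WRKY75. The other scalings moved the median log2 fold change by at most 0.026 in size. The labels number the replicates, and the numbers were taken to pair the libraries of a comparison where all same-number pairs had a correlation of deviations from the group means over 0.1. This held between the lines (4 of 4 pairs, 0.22 to 0.73) and for N2102363 against Col-0 with estradiol (3 of 3, 0.11 to 0.17), but for 2 of 3 pairs in each of estradiol in Col-0 and N2102362 against Col-0. Where it held, calls that changed with a replicate block are given beside the result; the mark was applied to each comparison after the calls were known. Unchanged groups were simulated 20 times against the shared controls. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.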

Results

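The series measured gene expression in rosettes of wild-type Col-0 and of N2102362 and N2102363, independent Arabidopsis lines in which estradiol induces the transcription factor WRKY75. It held 14 RNA-seq libraries: 3 of Col-0 sprayed with water, 3 of Col-0 sprayed with estradiol, and 4 of each line sprayed with estradiol. Total counts ran from 20670525 to 20680038 per library for Col-0 with water, from 20520901 to 20767791 for Col-0 with estradiol, from 20456036 to 20789232 for N2102362 and from 20559563 to 22605970 for N2102363. The lines were compared with wild type 3 h after the same spray, and the water spray served to measure the effect of estradiol in plants without the transgene.

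WRKY75, a WRKY-family transcription factor, was far higher in both sprayed lines than in Col-0. Lines without estradiol were not among the libraries, so a level present before the spray was not measured. The gene AT5G13080 lies on the minus strand of chromosome 5 from 4149740 to 4151150 (TAIR10). Its level was 0.875 ± 0.416 CPM (SD, n = 3) in Col-0 with water and 1.50 ± 1.07 CPM (n = 3) in Col-0 with estradiol, against 42.7 ± 26.3 CPM (n = 4) in N2102362 and 127 ± 39.3 CPM (n = 4) in N2102363. Against Col-0 with estradiol this was a log2 fold change of 4.85 ± 0.57 (SE) in N2102362 (adjusted p = 0.00458), 6.42 ± 0.60 in N2102363 (adjusted p = 0.000806) and 5.64 ± 0.57 in the mean of the lines (adjusted p = 0.000792). The counts do not separate transcripts of the native gene from those of the inducible copy. All 8 line libraries lay above all 3 Col-0 estradiol libraries. A two-sided exact permutation test of the levels gave p = 0.0286 for each line, the smallest that 4 against 3 allow, and p = 0.00606 for both lines together. In Col-0 itself estradiol gave a log2 fold change of 0.75 ± 0.72 (exact p = 0.5, where 3 against 3 allow no p below 0.1). The lines differed by 1.57 ± 0.40 on the log2 scale, which was not called (adjusted p = 1.000, exact p = 0.0571). N2102363 was higher in 4 of 4 pairs of the same replicate number (exact paired p = 0.125, the smallest that 4 pairs allow; adjusted p = 0.712 with a replicate block). In N2102362, replicates 1 to 3 lay between 28.2 and 30.7 CPM and replicate 4 at 82.1 CPM. The call in N2102362 was lost without Col-0 estradiol replicate 2 (log2 fold change 4.47, adjusted p = 0.0532) or replicate 3 (4.72, adjusted p = 0.0651), and in a fit of the compared groups alone (4.85, adjusted p = 0.150).

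**Figure D1:**
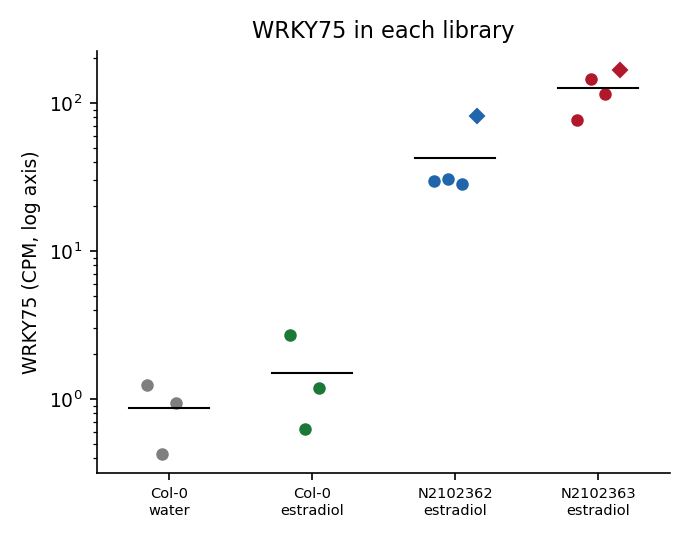
WRKY75 in each library in CPM on a log axis, by group; points are libraries, diamonds replicate 4 of the lines and bars group means. The line libraries lie at 28.2 CPM or above and the Col-0 libraries at 2.69 CPM or below.

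Besides WRKY75, AT1G42140 and TPPI rose and AT3G01345 and IRT3 fell in both lines against Col-0 with estradiol. AT3G01345 dropped from 143 ± 19.8 CPM (SD, n = 3) in Col-0 with estradiol, and 168 ± 22.5 CPM (n = 3) with water, to 0.217 ± 0.309 CPM (n = 4) in N2102362 and 0.189 ± 0.0828 CPM (n = 4) in N2102363. IRT3, a metal transporter of the ZIP family, dropped from 13.1 ± 4.85 CPM in Col-0 with estradiol, and 16.0 ± 4.24 CPM with water, to 0.626 ± 0.409 and 0.884 ± 0.439 CPM. The pseudogene AT1G42140 stood at 0.158 ± 0.0921 CPM in Col-0 with estradiol, and 0.275 ± 0.0809 CPM with water, against 1.55 ± 0.258 and 1.51 ± 0.150 CPM in the lines. TPPI, a gene of the trehalose-6-phosphate phosphatase family, stood at 1.18 ± 0.138 CPM in Col-0 with estradiol and 1.27 ± 0.259 CPM with water, against 3.44 ± 0.378 and 3.79 ± 0.593 CPM.

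In the mean of the lines, the log2 fold change was -9.44 ± 0.30 (SE) for AT3G01345 (adjusted p = 3.16e-09), -4.14 ± 0.35 for IRT3 (adjusted p = 0.000164), 3.20 ± 0.32 for AT1G42140 (adjusted p = 0.000779) and 1.60 ± 0.18 for TPPI (adjusted p = 0.00187). AT3G01345 (chromosome 3, 129138 to 130749, plus strand) had 2524 to 3904 counts in the Col-0 libraries and 1 to 14 in the line libraries. The 14 counts were in N2102362 replicate 1, at 0.680 CPM, against 0.0903 CPM or less in the other replicates of that line. IRT3 is AT1G60960 (chromosome 1, 22445310 to 22447214, minus strand), AT1G42140 lies on the minus strand of chromosome 1 from 15736521 to 15741101, and TPPI is AT5G10100 (chromosome 5, 3157980 to 3161708, plus strand). All are protein-coding genes in the annotation except AT1G42140, a pseudogene that resembled 112 other genes. Its counts were low, 1 to 7 per Col-0 library and 26 to 38 per line library, and its closest relative matched at 91.1% identity. TPPI in N2102362 lost its call without Col-0 estradiol replicate 1 (log2 fold change 1.46, adjusted p = 0.0917) or replicate 2 (1.52, adjusted p = 0.0733). In fits of the compared groups alone, TPPI, AT1G42140 and IRT3 lost their calls in both lines, with log2 fold changes of 1.53, 3.21 and -4.39 (adjusted p = 0.150, 0.150 and 0.0872) in N2102362 and 1.67, 3.18 and -3.89 (adjusted p = 0.103, 0.0864 and 0.0504) in N2102363.

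A further pair of genes was called lower in the mean of the lines. CYP81D5, a cytochrome P450 gene, was lost in N2102362 alone and is described with the comparison of the lines. AT2G01008 (chromosome 2, 1025 to 2810, plus strand) had a log2 fold change of -2.39 ± 0.35 (adjusted p = 0.0304), from 9.76 ± 5.07 CPM (SD, n = 3) in Col-0 with estradiol to 2.49 ± 1.44 CPM (n = 4) in N2102362 and 1.37 ± 0.398 CPM (n = 4) in N2102363. It was not called in either line by itself (adjusted p = 0.589 in N2102362 and 0.0569 in N2102363), but was called in N2102363 with a replicate block (log2 fold change -2.60 ± 0.32, adjusted p = 0.0237). Its level is uncertain, because 7 other genes matched it at 95% identity or more, the closest being AT3G41762 at 99.1% over 1419 bases. The call was lost without any of 11 libraries in turn, with log2 fold changes from -1.91 to -2.47 and adjusted p from 0.0503 without N2102363 replicate 2 to 0.435 without Col-0 estradiol replicate 1, without replicate 4 of both lines (-2.22, adjusted p = 0.119), and in a fit of the compared groups alone (-2.39, adjusted p = 0.0850).

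Of 19666 genes tested, edgeR called 6 in N2102362 (3 higher, 3 lower), 5 in N2102363 (3 higher, 2 lower) and 7 in the mean of the lines (3 higher, 4 lower), all with an absolute log2 fold change of at least 1. At an unadjusted p under 0.05 there were 914, 2205 and 1834 genes, where 983 would pass by chance. These counts depended on single libraries: without Col-0 estradiol replicate 1 they were 458, 1225 and 836. N2102362 had 1448 without Col-0 estradiol replicate 2, 1419 without its replicate 2 and 508 without its replicate 4, and N2102363 had 1330 without its replicate 4. Without replicate 4 of both lines there were 525, 1740 and 1174. DESeq2 called 9, 37 and 27 genes. With both Col-0 groups as reference, and so 6 control libraries in place of 3, 127 genes were called in the mean of the lines; against the 3 Col-0 water libraries alone there were 11. Without replicate 4 of both lines, 7, 7 and 7 genes were called. Without Col-0 estradiol replicate 3, N2102363 gave 8 calls. With a replicate block it gave 7, the added ones being AT2G01008 and ZIFL1, a membrane transporter gene (log2 fold change -1.33 ± 0.12, adjusted p = 0.00314; -1.52 ± 0.25 and 0.107 without the block). Called in both lines in the same direction were 3 higher genes, WRKY75 itself among them, and 2 lower genes. Independent lists of these sizes would share 0.000458 and 0.000305, but the lines share their controls. In 20 simulations of unchanged groups with the shared controls the number was 0. These simulations gave too few calls for any overlap, so they do not test it. Of 100 splits of the real libraries, 4 reached 5 such genes and the highest other 1232. Without Col-0 estradiol replicate 2 the number in both lines was 3.

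Across all tested genes, fold changes of the lines went together. Their correlation was 0.747, against 0.580 (0.556 to 0.606) in unchanged groups simulated with the same 3 controls, and the covariance was 0.0780 against 0.0424. The 2 lines had the same sign for 79.5% of genes, against 69.5% simulated. When N2102362 was set against Col-0 with estradiol and N2102363 against Col-0 with water, the correlation was 0.469 and the covariance 0.0630. The number of shared calls was again 3 higher and 2 lower. The simulated values hold for shared controls and are no reference for this setting, which was not simulated. It also sets sprayed N2102363 against Col-0 without estradiol, so the spray differs on that side. The 3 shared controls are too few to split, so part of the excess over the simulation may come from them. The simulation also left out what the lines share by replicate number, and their replicate 4, which Col-0 lacks, and part of the excess may come from these. Genes are not independent replicates.

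**Figure D2:**
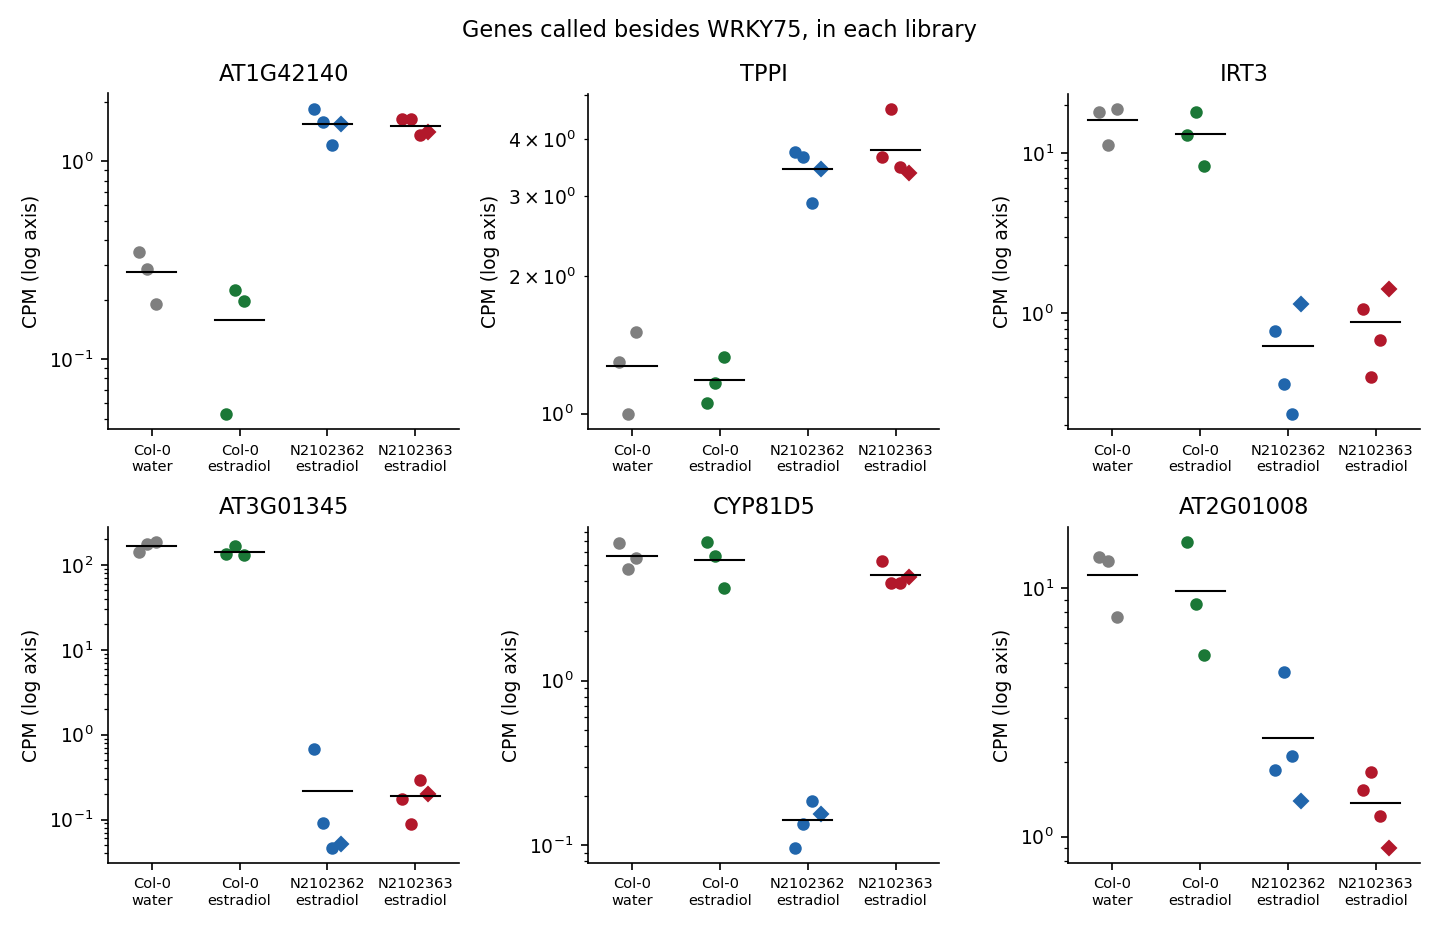
Levels of the other called genes in CPM (log axes) in each library; points are libraries, diamonds replicate 4 of the lines and bars group means. AT3G01345 and IRT3 lie lower, and AT1G42140 and TPPI higher, in all 8 line libraries than in the 6 Col-0 libraries, and CYP81D5 is low in N2102362 but not in N2102363.

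WRKY proteins bind the W-box, and the promoters of the called genes were searched for it. In the mean of the lines, 1 of 3 higher genes (33.3%) and 1 of 4 lower genes (25.0%) had a W-box within 500 bp, against 44.4% of 19551 other genes tested (two-sided Fisher's exact p = 1.00 and 0.634). The higher gene with a W-box was WRKY75 itself, the gene of the inducible construct; without it 0 of 2 had one (Fisher's exact p = 0.506), a count made after the data were seen. A control motif of the same base composition was present in 0 of 3 and 0 of 4, against 35.9% (Fisher's exact p = 0.557 and 0.304). In a test added because few genes were called, the 8688 genes with a W-box had a median log2 fold change of -0.01 and the 10870 without it a median of 0.00 (camera p = 0.502 at the preset correlation, p = 0.269 with an estimated correlation). With so few called genes, the search could detect no moderate enrichment.

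In the mean of the lines against Col-0 with estradiol, the camalexin, jasmonate, xenobiotic, senescence and abscisic acid lists were called lower. Lists of dividing cells and floral genes were called higher, all at the preset correlation. Other defence and stress lists were not called, as given below. The camalexin and indole glucosinolate list, which covers tryptophan-derived defence compounds, was lower in 16 of 19 measured members, with a median log2 fold change of -0.38 (camera, adjusted p = 0.000110; adjusted p = 0.540 with an estimated correlation). Values were -0.60 ± 0.20 (SE) for GGP1, -0.46 ± 0.15 for SUR1 and -0.38 ± 0.16 for CYP79B2, all of which act in the synthesis of these compounds. In the jasmonate list 27 of 28 members were lower, with a median of -0.35 (adjusted p = 0.00231; adjusted p = 0.540 with an estimated correlation). The biosynthesis genes LOX3 and OPR3 had values of -0.95 ± 0.34 and -0.95 ± 0.36. Against Col-0 with water the jasmonate list was higher in 19 of 28 (median 0.19, adjusted p = 0.656). The xenobiotic detoxification list was lower in 17 of 20 (median -0.32, adjusted p = 0.00672, and adjusted p = 0.540 with an estimated correlation). GSTF8, a glutathione transferase gene, stood at -0.31 ± 0.11 and OPR2 at -0.68 ± 0.25. Against Col-0 with water this list had 12 of 20 members higher (median 0.10), while the test pointed down (adjusted p = 0.740).

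Leaf senescence genes were lower in 15 of 19 (median -0.23, adjusted p = 0.0211; adjusted p = 0.540 with an estimated correlation), SAG20 at -0.37 ± 0.20 (SE) among them. Genes of abscisic acid, drought and cold were lower in 14 of 17 (median -0.22, adjusted p = 0.0234; adjusted p = 0.540 with an estimated correlation), with -0.51 ± 0.17 for RAB18, a dehydrin gene. Against Col-0 with water this list was higher in 11 of 17 (median 0.22, adjusted p = 0.365). The directions of the jasmonate and abscisic acid lists thus turned with the reference. For the xenobiotic list only the median turned, while the test still pointed down. Markers of dividing cells were higher in 7 of 7 (median 0.49, adjusted p = 0.00250; adjusted p = 0.540 with an estimated correlation), including the cell cycle genes CYCA1;1 at 0.57 ± 0.23 and CDKB2;1 at 0.58 ± 0.25. This list was also higher in replicate 4 than in the other replicates of the lines (7 of 7, median 0.56, adjusted p = 0.0110, and adjusted p = 0.485 with an estimated correlation). Floral markers were higher in 4 of 5 (median 0.51, adjusted p = 0.0211; adjusted p = 0.394 with an estimated correlation), among them SOC1, a flowering-time regulator, at 0.32 ± 0.10, and PI, a floral organ identity gene, at 1.12 ± 0.56 with 2.01 CPM or less in every line library. None of the members named was called over all genes. Adjusted over the list alone, SOC1 was higher and APX1, an ascorbate peroxidase gene at -0.56 ± 0.15, was lower.

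The other 14 lists were not called in the mean of the lines. Ethylene and ERF-branch defence had a median log2 fold change of -0.33 (adjusted p = 0.0555), phosphate starvation -0.10 (0.0678), oxidative stress and peroxidases -0.15 (0.150), touch, wound and early immune response -0.27 (0.124), and aliphatic glucosinolates -0.11 (0.177). Early auxin response had a median of 0.09 (0.0985), photosynthesis 0.12 (0.126), salicylic acid 0.09 (0.614), the clock -0.02 (0.947), brassinosteroids 0.00 (0.902) and the other WRKY genes -0.01 (0.426). Root markers had a median of 0.15 (0.108), guard cell markers 0.11 (0.426) and vascular markers 0.21 (0.186). The brassinosteroid and WRKY medians lay slightly under 0 while the test pointed up. PR1, a marker of salicylic acid signalling, had a value of 2.89 ± 0.94 (SE; adjusted p = 0.520) with much spread, from 6.53 CPM in N2102362 replicate 4 to 94.7 CPM in N2102363 replicate 1. RBOHF, an NADPH oxidase gene, stood at 0.51 ± 0.22, IAA3 at 0.40 ± 0.13, PYK10 at 0.63 ± 0.28, SUC2 at -0.29 ± 0.12, and the clock genes LNK2 and RVE1 at 0.71 ± 0.27 and 1.06 ± 0.48. Replicate 4, which Col-0 lacks, carried part of these values. Against the other replicates of the lines, RBOHF, PYK10, LNK2 and RVE1 were called higher in it, with log2 fold changes of 0.65, 0.83, 0.88 and 1.45. IAA3 and SUC2 were not called there.

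In N2102362 alone, lists called lower against Col-0 with estradiol were jasmonate (26 of 28 members, adjusted p = 0.000327), camalexin and indole glucosinolates (17 of 19, 0.000327), xenobiotic detoxification (19 of 20, 0.000287), senescence (16 of 19, 0.00211), abscisic acid, drought and cold (13 of 17, 0.0167) and ethylene (20 of 25, 0.0398). Dividing cells were called higher (7 of 7, 0.00573). With an estimated correlation these had adjusted p = 0.448, and 0.584 for ethylene. In N2102363 camalexin and indole glucosinolates (17 of 19, 0.000207), jasmonate (25 of 28, 0.0149) and aliphatic glucosinolates (17 of 19, 0.0149) were called lower, and dividing cells (7 of 7, 0.00347), floral markers (4 of 5, 0.0118) and early auxin response (8 of 10, 0.0197) higher. With an estimated correlation these had adjusted p = 0.595 for camalexin, dividing cells and auxin, 0.711 for jasmonate and aliphatic glucosinolates, and 0.198 for floral markers. Adjusted over the list alone, APX1 was lower and SOC1 higher in N2102363, and 0 members passed in N2102362.

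In the mean of the lines the camalexin call held with each library left out in turn, and each of the other 6 was lost without at least 1 library. Without Col-0 estradiol replicate 1, the xenobiotic, senescence and abscisic acid lists had adjusted p = 0.185, 0.148 and 0.148. Without Col-0 estradiol replicate 2, dividing cells and floral markers had adjusted p = 0.0940 and 0.0518. Without Col-0 estradiol replicate 3, jasmonate, senescence, abscisic acid and floral markers had adjusted p = 0.153, 0.0564, 0.0547 and 0.0616. Leaving out N2102363 replicate 3 took the number of lists from 7 to 4 and the abscisic acid list to adjusted p = 0.108, with senescence and xenobiotic detoxification at 0.0579. The other losses, without N2102362 replicates 2, 3 or 4 or N2102363 replicate 4, were of floral markers, xenobiotic detoxification, abscisic acid and senescence, with adjusted p from 0.0565 to 0.0667.

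The camalexin call also held with each library left out in either line by itself, as did those of dividing cells and floral markers in N2102363. The jasmonate call was lost in N2102362 without Col-0 estradiol replicate 3 (adjusted p = 0.0885) and in N2102363 without that library (0.325), Col-0 estradiol replicate 1 (0.0930) or N2102363 replicate 3 (adjusted p = 0.544). In N2102362 the xenobiotic and abscisic acid calls were lost without N2102362 replicate 3 (adjusted p = 0.0508 and 0.0736), abscisic acid also without Col-0 estradiol replicate 1 (0.101), dividing cells without Col-0 estradiol replicate 2 (0.256) or N2102362 replicate 4 (0.152), and senescence without the latter (adjusted p = 0.0843). Ethylene was lost there without Col-0 estradiol replicates 1 or 2 or N2102362 replicates 2, 3 or 4, with adjusted p from 0.0622 to 0.460. In N2102363 aliphatic glucosinolates had adjusted p = 0.472 without Col-0 estradiol replicate 1, 0.0510 without N2102363 replicate 2 and 0.212 without N2102363 replicate 3. Auxin had adjusted p = 0.248 without Col-0 estradiol replicate 2 and 0.0888 without N2102363 replicate 2. Leaving out N2102362 replicate 3 gave 4 lists in place of 7 in N2102362, and leaving out N2102363 replicate 1 gave 13 in place of 6 in N2102363. A replicate block in N2102363 added the salicylic acid (16 of 24 higher, median 0.22), xenobiotic (7 of 20 higher, median -0.22) and WRKY lists (25 of 32 higher, median 0.18), with adjusted p = 0.00198, 0.0403 and 0.00180; with an estimated correlation these had adjusted p = 0.544, 0.611 and 0.544. With both Col-0 groups as reference, 2 lists were called in the mean of the lines and 3 in N2102362. In the mean those of jasmonate, senescence, xenobiotic detoxification, abscisic acid and floral markers were lost (adjusted p = 0.388, 0.370, 0.208, 0.907 and 0.163). Without replicate 4 of both lines 9 lists were called in the mean of the lines, while the senescence call was lost there (adjusted p = 0.233), and in N2102362 those of senescence, ethylene and dividing cells were lost (adjusted p = 0.0955, 0.418 and 0.127).

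Replicate 4 of both lines stood apart from the other libraries. On the first principal component, with 39.5% of the variance, replicate 4 of N2102362 scored 57.3 and that of N2102363 51.4. The scores of all other libraries lay at 29.2 or below, and at the other end Col-0 water replicate 2 scored -49.7 and Col-0 estradiol replicate 2 -44.3. Within the lines, edgeR called 2481 of 19666 genes in replicate 4 against replicates 1 to 3, 1301 higher and 1180 lower. Clock genes were prominent, with 7 called higher and 10 lower of 22. The morning genes LHY and CCA1 were higher, by 1.79 ± 0.14 (SE; adjusted p = 0.00643) and 1.29 ± 0.19 (adjusted p = 0.00952) on the log2 scale. The evening genes TOC1, ELF4 and FKF1 were lower, with log2 fold changes of -0.98 ± 0.13 (adjusted p = 0.00778), -3.92 ± 0.59 (adjusted p = 0.00849) and -4.31 ± 0.76 (adjusted p = 0.0153). Of 25 photosynthesis genes 17 were called higher and 0 lower. Of the camalexin list 9 of 19 were called lower and 1 higher, of senescence 8 of 19 lower, of salicylic acid 6 of 24 lower, and of aliphatic glucosinolates 7 of 19 higher. The jasmonate list was higher in 22 of 28 (median 0.40, adjusted p = 0.0235), opposite to its direction in the lines against Col-0 with estradiol. No list was called in replicate 4 with an estimated correlation, the lowest adjusted p being 0.434. The Col-0 groups held no replicate 4.

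**Figure D3:**
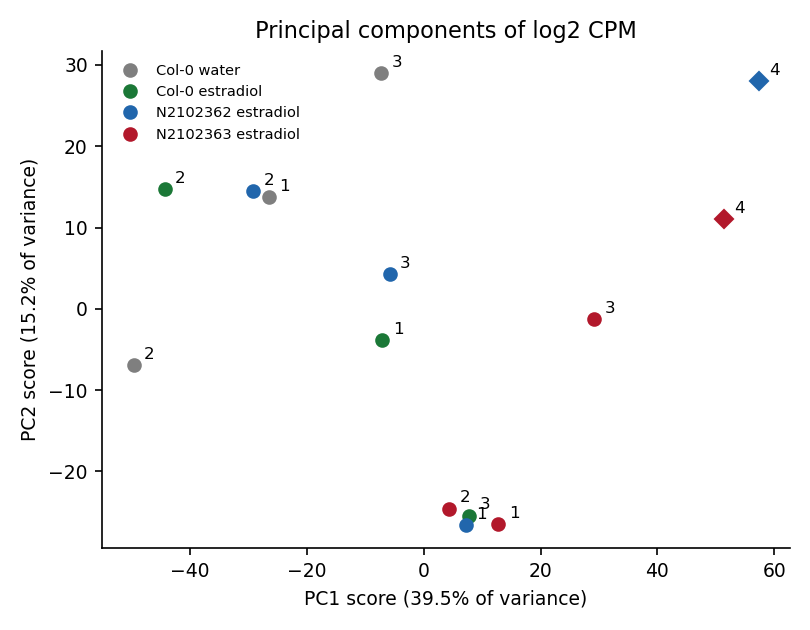
Scores of the 14 libraries on the first and second principal components of log2 CPM, with the share of variance on each axis; colours mark the groups, numbers the replicates and diamonds replicate 4 of the lines. Replicate 4 of both lines lies at scores of 51.4 and 57.3 on the first component.

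**Figure D4:**
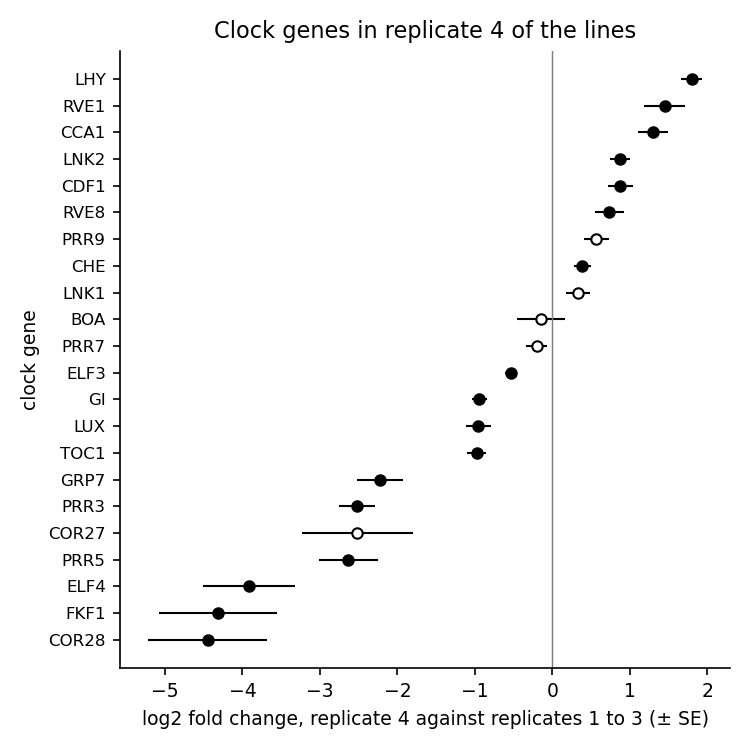
Log2 fold change of 22 clock genes between replicate 4 and replicates 1 to 3 within the lines; bars are SE and filled points have an adjusted p under 0.05. LHY and CCA1 lie at 1.79 and 1.29, and ELF4 and FKF1 at -3.92 and -4.31.

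The comparison of estradiol with water in Col-0 measured what the inducer spray does in plants without the transgene. No single gene was called, but 8 lists of stress and hormone genes were shifted higher. In the jasmonate list 27 of 28 members were higher, with a median log2 fold change of 0.53 (camera, adjusted p = 8.83e-09; adjusted p = 0.400 with an estimated correlation). CYP94B3, a gene of jasmonate turnover, had a value of 4.19 ± 1.44 (SE) and JAZ10, a repressor of jasmonate signalling, 1.66 ± 0.78. Genes of abscisic acid, drought and cold were higher in 15 of 17 (median 0.22, adjusted p = 8.83e-09; adjusted p = 0.209 with an estimated correlation), with 2.07 ± 0.61 for the cold-induced gene KIN1.

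The touch, wound and early immune list was higher in 17 of 21 (adjusted p = 2.53e-05; adjusted p = 0.637 with an estimated correlation), with RAP2.6 at 3.16 ± 0.90 (SE). Also called higher were the other WRKY genes (22 of 32, adjusted p = 0.00229), with WRKY22 at 0.77 ± 0.33 and WRKY29 at 0.61 ± 0.19, senescence (14 of 19, 0.00359) and xenobiotic detoxification (19 of 20, 0.00359), with UGT75B1 at 0.50 ± 0.31. With an estimated correlation these had adjusted p = 0.637. Oxidative stress and peroxidases were higher in 13 of 16 (adjusted p = 0.00671; adjusted p = 0.400 with an estimated correlation), with PRX71 at 0.73 ± 0.25. Ethylene and ERF-branch defence was higher in 18 of 25 (adjusted p = 0.0366; adjusted p = 0.682 with an estimated correlation), with ACS7, an ethylene biosynthesis gene, at 1.18 ± 0.47. The median and the test differed in sign for the salicylic acid and floral lists, which were not called (adjusted p = 0.938 and 0.591).

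edgeR called 0 of 19666 genes for estradiol in Col-0. At an unadjusted p under 0.05 there were 310 genes, where 983 would pass by chance. That count was 482 without Col-0 water replicate 2, and 553, 1047 and 163 without Col-0 estradiol replicates 1, 2 and 3, so that its relation to chance rested on 1 library. DESeq2 called 0 genes, with 368 at an unadjusted p under 0.05. Adjusted over the list alone, 0 list members passed. The jasmonate and abscisic acid calls held with each library left out in turn, and each of the other 6 was lost without at least 1. The number of lists fell from 8 to 5 without Col-0 water replicate 3 and to 5 without Col-0 estradiol replicate 1. Senescence was lost in both cases (adjusted p = 0.524 and 0.282), as was ethylene (adjusted p = 0.665 and 0.260), which was also lost without Col-0 estradiol replicate 2 (adjusted p = 0.317). Without Col-0 estradiol replicate 1 or Col-0 water replicate 2, the xenobiotic list had adjusted p = 0.441 and 0.187 and the oxidative list 0.190 and 0.0521. Without Col-0 water replicate 1, Col-0 water replicate 3 or Col-0 estradiol replicate 2, the touch list had adjusted p = 0.196, 0.0906 and 0.107 and the WRKY list 0.196, 0.193 and 0.153. The WRKY list was also lost without Col-0 estradiol replicate 3 (adjusted p = 0.226). The Col-0 estradiol libraries were also the reference of the lines. Against Col-0 with water, the jasmonate list of the lines had a median of 0.19 (camera p = 0.437) and the camalexin and indole glucosinolate list -0.51 (adjusted p = 0.000419; adjusted p = 0.930 with an estimated correlation).

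In the main fit, CYP81D5 was the sole gene called between the lines. It stood at 0.143 ± 0.0376 CPM (SD, n = 4) in N2102362, against 4.35 ± 0.671 CPM (n = 4) in N2102363, 5.42 ± 1.65 CPM (n = 3) in Col-0 with estradiol and 5.71 ± 1.06 CPM (n = 3) with water. It had 2 to 4 counts per library in N2102362 and 74 to 137 in the other groups. The log2 fold change of N2102363 against N2102362 was 4.87 ± 0.29 (SE; adjusted p = 6.29e-06). Against Col-0 with estradiol it was -5.18 ± 0.30 in N2102362 (adjusted p = 1.91e-06) and -0.31 ± 0.21 in N2102363 (adjusted p = 0.543). CYP81D5 is the protein-coding gene AT4G37320 on the minus strand of chromosome 4, from 17559580 to 17561727. Its neighbours CYP81H1 and CYP81D4, 636 and 617 bp away, had log2 fold changes of -0.14 ± 0.17 and -0.16 ± 0.15 in N2102362.

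Between the lines, aliphatic glucosinolate genes, which make methionine-derived defence compounds, were lower in N2102363 in 19 of 19 members, with a median log2 fold change of -0.34 (camera, adjusted p = 1.12e-05; adjusted p = 0.964 with an estimated correlation). Values were -0.53 ± 0.28 (SE) for CYP83A1, -0.38 ± 0.16 for SOT17 and -0.81 ± 0.54 for MAM3. Early auxin response genes were higher in 8 of 10 (median 0.22, adjusted p = 0.00854), GH3.3 at 0.53 ± 0.23 among them, and the other WRKY genes in 25 of 32 (median 0.18, adjusted p = 0.00992), WRKY28 at 0.83 ± 0.40 among them. With an estimated correlation both had adjusted p = 0.964. None of these members was called over all genes or adjusted over the list alone. All 3 calls were lost without at least 1 library. Without N2102362 replicate 4 the aliphatic glucosinolate and WRKY lists had adjusted p = 0.102 and 0.642, and the WRKY list had adjusted p = 0.532 without N2102363 replicate 1 and 0.0901 without N2102363 replicate 2. The auxin list had adjusted p = 0.283 without N2102362 replicate 2 and 0.0689 without N2102363 replicate 2. The number of lists rose from 3 to 5 without Col-0 estradiol replicate 2 or N2102363 replicate 4, to 6 without N2102362 replicate 4 or N2102363 replicate 1, and to 7 without N2102363 replicate 3. DESeq2 called 4 genes. Among them was AT5G24240, at -4.57 ± 0.78 (SE) in N2102363 against N2102362 (DESeq2, adjusted p = 6.04e-05). In N2102362 against Col-0 with estradiol it stood at 4.43 ± 0.85 (DESeq2, adjusted p = 0.000518). The edgeR fit of all libraries did not call it (adjusted p = 0.966 and 0.852), but called it in both comparisons without N2102362 replicate 4. At an unadjusted p under 0.05, 461 genes differed between the lines where 983 would pass by chance. The count at an unadjusted p was 918, 205, 273 and 1325 without N2102362 replicates 1, 2, 3 and 4, and 1289 with a replicate block, so it did not stay below chance. The block also called ZIFL1, lower in N2102363 by a log2 fold change of -1.22 ± 0.11 (adjusted p = 0.00298; -1.25 ± 0.24 and 0.875 without it), and the floral list (4 of 5 higher, median 0.23, adjusted p = 0.0468; adjusted p = 0.789 with an estimated correlation).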

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

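Chosen after the results were seen were the tests of WRKY75 level, of a shared day for replicate 4, of repression within the time after the spray, of differences present before it, of the shared Col-0 libraries, of a spray effect on all plants and of the splits that part same-number pairs; the splits of the libraries and the tests of near-identical genes, neighbouring genes, the time of day and single Col-0 libraries were set before their results.

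The genes called in both lines besides WRKY75, AT3G01345, IRT3, AT1G42140 and TPPI, could in principle share reads with copies elsewhere or lie in lost or gained segments. Of these genes 0 had a near-identical gene, which argues against shared reads for AT3G01345, IRT3 and TPPI. AT1G42140 resembled 112 other genes, the closest at 91.1% identity over 4596 bases. Identity was taken over whole matches, so reads shared through shorter identical stretches stay open for AT1G42140. The nearest tested genes had a median absolute log2 fold change of 0.10, which argues against lost or gained segments that reach these neighbours. A change confined to the gene stays open. A segment holding untested genes stays open for AT1G42140, whose nearest tested genes lay 83978 and 72742 bp away. It also stays open on 1 side of IRT3, where the nearest lay 14811 bp away. Repression by WRKY75 after the spray would need an AT3G01345 transcript with a half-life of at most 19.1 minutes, and no half-life was measured. A difference already present before the spray cannot be told apart from it, because 0 line libraries without estradiol were analysed. The loss of CYP81D5 in N2102362 alone had a log2 fold change between the lines of 4.87, a difference tested between them. N2102363, which kept the gene, had WRKY75 at 76.8 to 167 CPM, against 28.2 to 82.1 CPM in N2102362. This argues against WRKY75 level as the cause, but the WRKY75 difference between the lines was not called and the ranges overlap. The loss was also not explained by shared reads (0 near-identical genes) or a lost segment of several genes (the lower of its neighbours at -0.16). A loss confined to CYP81D5 was not tested.

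Replicate 4 stood apart in both lines. WRKY75 level cannot be told apart from it as a cause, because replicate 4 had the most WRKY75 in both lines (82.1 and 167 CPM). Across the lines the order differed. N2102363 replicates 2 and 3 had WRKY75 at 146 and 116 CPM but scored 4.35 and 29.2 on the first principal component. N2102362 replicate 4, at 82.1 CPM, scored 57.3. Among replicates 1 to 3 within the lines, WRKY75 and that component correlated at -0.16. These libraries were too few to decide (one-sided exact p = 0.389 for a negative and 0.639 for a positive correlation). A shared day or batch cannot be told apart either: the deviations of the replicate 4 libraries correlated at 0.731, which any shared cause would give, and 0 Col-0 libraries of replicate 4 were there to decide. The deviations of Col-0 water replicate 3 correlated with theirs at 0.577 in N2102362 and 0.504 in N2102363. The shared deviation was thus not confined to replicate 4. A harvest at another time of day stays open. The clock list had a median absolute log2 fold change of 0.97 between replicate 4 and the others. This lay at percentile 100 of 10000 random lists matched on expression, whose median was 0.22. Lists of other functions also moved far, with medians of -1.22 for salicylic acid (0 of 24 members higher) and -0.79 for touch (0 of 21). The percentile thus does not set a time of day apart from other causes. A shared day and a time of day cannot be separated here, and no biological explanation other than WRKY75 was tested.

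At the preset correlation, the jasmonate, abscisic acid, xenobiotic and senescence lists were called higher in estradiol-sprayed Col-0. In the mean of the lines against it they were called lower. The touch, oxidative, ethylene and WRKY lists were also called higher in Col-0 but were not called in the mean of the lines. With an estimated correlation none of these calls held. In log2 units over the mean of the water libraries, 2 of 3 Col-0 estradiol libraries had a jasmonate median above the highest water library, at 0.61 and 0.98 against 0.47, and the other lay at -0.02, which leaves open an effect of single libraries. Against Col-0 with water the lines showed no called shift of the jasmonate list (19 of 28 members higher, camera at the preset inter-gene correlation, p = 0.437, adjusted p = 0.656). Of the other lists, abscisic acid had a median of 0.22 (11 of 17 higher, adjusted p = 0.365) and senescence -0.03 (9 of 19 higher, adjusted p = 0.812). Xenobiotic detoxification had a median of 0.10 with 12 of 20 higher, while its test pointed down (adjusted p = 0.740). The Col-0 estradiol libraries may thus be the source of these falls in the lines, although a p above the threshold does not show that the lists were equal. An effect of the spray on all sprayed plants stays open too, since the lines had a median of 0.19 over Col-0 with water.

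Splits of the same libraries into groups of the same sizes were run for each comparison. For estradiol in Col-0, the 10 splits are too few for a share under 0.05; the real split called 0 genes with edgeR (310 at an unadjusted p under 0.05, and 0 with DESeq2) and the highest other 3, and 10 of 10 splits called at least as many, while for lists 3 of 10 splits gave as many as the real 8, with 10 the highest other. For N2102362, 3 of 35 splits called as many genes as the real 6, so chance could not be excluded for that count, which does not bear on single genes, and the highest other called 476. That split set Col-0 estradiol replicate 2 and N2102362 replicates 2 and 3 apart, and another, with Col-0 estradiol replicates 1 and 2 and N2102362 replicate 2 apart, called 44. For N2102363, 1 of 35 splits, the real one, reached 5 genes and the highest other 0. That share was under 0.05. The 35 splits ignore the replicate numbers that pair these groups, so chance was not excluded for that count. Of the 35 splits, the 8 that part all 3 same-number pairs are too few for a share under 0.05. Among these 8, the real one called 5 genes and the highest other 0, and 6 and 13 lists. For the mean of the lines, 4 of 100 splits reached 7 genes, and for genes called in both lines 4 of 100 reached 5. Both shares were under 0.05, but these splits also ignore the replicate numbers, so chance was not excluded. Other splits called up to 3519 and 1232. The split with 3519 set N2102362 replicate 4 and both N2102363 replicates 3 and 4 apart, so replicate 4 of both lines lay on 1 side, and the 2 splits of Col-0 estradiol and N2102362 libraries just named called 1265 and 826 genes. Such counts point to a structure of the samples other than the groups. The mean of the lines called 7 genes without replicate 4 of both lines, 7 with an indicator for replicate 4, chosen after the data were seen, and 8 with a replicate block. Between the lines 2 of 35 splits reached 1 gene, with 1 the highest other, so chance was not excluded for a count of 1; the gene was CYP81D5 (adjusted p = 6.29e-06). The 8 splits that part all 4 same-number pairs are again too few, with 1 gene for the real one and 0 the highest other, and 3 and 11 lists.

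For the gene lists, chance could not be excluded in any line comparison. As many lists as the real 7 were called by 21 of 35 splits in N2102362 (highest other 11), as many as 6 by 24 of 35 in N2102363 (highest other 13), as many as 7 by 57 of 100 in the mean of the lines (highest other 14), and as many as 3 by 35 of 35 between the lines (highest other 15). The aliphatic glucosinolate, early auxin and WRKY lists drew notice because they differed between the lines, with medians of -0.34, 0.22 and 0.18 in N2102363 against N2102362 and adjusted p = 1.12e-05, 0.00854 and 0.00992 at the preset correlation. All 3 had adjusted p = 0.964 with an estimated correlation and 0.999 with fry.

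In 12 of 104 groups of 4 values, 1 library lay far from the rest by Dixon's gap (critical value 0.829). In independent groups not chosen by their values, chance gives about 1 in 20, or 5.20. The genes covered were among those named here, many of them chosen after their values were seen. They also share libraries, so 12 against 5.20 does not test chance. In replicate 4 the values far from the rest were WRKY75 at 82.1 CPM, LNK2 at 799 CPM and LHY at 22.7 CPM in N2102362, and CCA1 at 69.1 CPM and LHY at 19.7 CPM in N2102363. In N2102362 replicate 1 they were AT3G01345 at 0.680 CPM, SOC1 at 64.4 CPM and WRKY28 at 6.85 CPM, and in N2102362 replicate 2 OPR2 at 10.5 CPM. In N2102363 they were KIN1 at 2.69 CPM and PR1 at 94.7 CPM in replicate 1 and PI at 1.11 CPM in replicate 2.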

How the results depend on the processing

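The tests with an indicator for replicate 4, with independent Col-0 controls for the genes called in both lines, of the W-box genes as 1 set and of the higher genes with WRKY75 left out were chosen after the data were seen. Of the results that answer a comparison, 237 alternative values stayed within 1.5 times the reported count or kept their direction, 34 moved further and 2 turned; for single genes and lists 1052 kept their call and direction and 172 lost the call, and 0 turned. The other scalings, the filters and the stricter threshold moved no count of genes by over 1.5 times. In fits of the compared groups alone, the calls were 2 in N2102362, 2 in N2102363 and 1 in both lines; these fits hold fewer libraries. DESeq2 called 37 genes in N2102363, 27 in the mean of the lines and 4 between the lines; the cause was not tested. With both Col-0 groups as reference, which holds 6 control libraries in place of 3, 55 genes were called in N2102363 and 127 in the mean of the lines, and 3 and 2 lists in N2102362 and the mean. With an estimated correlation 0 lists were called in all 5 comparisons, and with fry 0 for estradiol in Col-0, 0 in N2102362, 1 in N2102363, 1 in the mean and 0 between the lines; the cause was not tested. The W-box share turned from below to above the background for higher genes within 200 bp (33.3%, against 24.1%) and for lower genes with at least 2 sites (25.0%, against 14.4%), with 1 gene in each set, WRKY75 itself among the higher genes.

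Leaving out 1 library, or replicate 4 of both lines, gave 0 called genes for estradiol in Col-0, 4 to 7 in N2102362, 5 to 8 in N2102363 (8 without Col-0 estradiol replicate 3), 6 to 8 in the mean, 1 to 2 between the lines (2 without N2102362 replicate 4) and 3 to 6 in both lines (3 without Col-0 estradiol replicate 2). Lists ran from 5 to 9 for estradiol in Col-0 (5 without water replicate 3 or estradiol replicate 1), 4 to 10 in N2102362 (4 without its replicate 3), 4 to 13 in N2102363 (13 without its replicate 1), 4 to 9 in the mean (4 without N2102363 replicate 3) and 3 to 7 between the lines (7 without N2102363 replicate 3). Of all same-number pairs, 16 of 19 correlated above 0.1, the lowest at -0.20, and 11 of 14 libraries correlated best with their own number, a hint from the data. With a replicate block the lines differed in 2 genes in place of 1, and other counts of calls stayed within 1.5 times. In the comparisons that the numbers did not pair, the block gave 0 genes for estradiol in Col-0, 7 in N2102362 and 8 in the mean, and ethylene in Col-0 (adjusted p = 0.117) and senescence in the mean (adjusted p = 0.139) were not called. In the paired ones it changed no call beyond those given with the results. At 20456036 counts or more per library, 1 count was about 0.05 CPM, so that the levels of AT3G01345 and CYP81D5 in their low groups rest on 1 to 14 counts.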

Other observations

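The set of respiratory chain genes, the comparison with both Col-0 groups as a list of genes and the comparison of the lines with Col-0 water were tested after the results were seen; the use of both Col-0 groups as reference was planned.

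With both Col-0 groups as reference, edgeR called 52 genes higher and 75 lower in the mean of the lines, 21 of them with an absolute log2 fold change of at least 1. Against Col-0 with estradiol alone 7 genes were called, and the genes named here were chosen after their values were seen. Among the higher genes were ESM1, a modifier of glucosinolate breakdown, at 1.15 ± 0.19 (SE; adjusted p = 0.0315), and SHP1, a MADS-box gene of fruit development, at 1.68 ± 0.21 (adjusted p = 0.00457) with a mean of 0.884 CPM. Lower genes included the metallothionein gene MT2B at -0.83 ± 0.15 (adjusted p = 0.0404) and the glutathione transferase gene GSTU13 at -0.95 ± 0.19 (adjusted p = 0.0457). ZIFL1, a membrane transporter gene, stood at -0.93 ± 0.18 (adjusted p = 0.0422). Its fall lay largely in N2102363, at -1.52 ± 0.25 against Col-0 with estradiol and -1.25 ± 0.24 against N2102362 (adjusted p = 0.107 and 0.875). APX1, the sole called gene that was in the lists, stood at -0.62 ± 0.12 (adjusted p = 0.0456). AT2G01021, near the start of chromosome 2 like AT2G01008, stood at -1.62 ± 0.30 (adjusted p = 0.0404). Against Col-0 with water alone, 11 genes were called, 5 higher and 6 lower, with 4161 at an unadjusted p under 0.05.

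A hypothesis from these genes is that nuclear genes of the mitochondrial respiratory chain may be slightly lower in the lines. Of 49 such genes, taken by product name, 41 had a negative log2 fold change against both Col-0 groups, with a median of -0.14 and 4 called lower. Camera gave p = 5.41e-10 at the preset correlation and p = 0.0593 with an estimated correlation, but the 4 called genes had prompted the set. Without them 37 of 45 were negative (median -0.13), with p = 2.38e-07 at the preset and p = 0.0887 with an estimated correlation, so the set test does not settle it. Without replicate 4 of both lines 43 were negative but 0 were called lower, with a median of -0.15 (camera p = 0.0544 with an estimated correlation). With an estimated correlation, the set gave p = 0.106 against Col-0 with estradiol alone (42 negative, median -0.11) and p = 0.0484 against Col-0 with water alone (43 negative, median -0.18). In Col-0 itself 37 were negative after estradiol, with a median of -0.06 (p = 2.27e-05 at the preset and p = 0.172 with an estimated correlation), so the preset also gave a low p in plants without the transgene.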
